A study of Homo sapiens with 10 samples.

How the data were processed

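RNA sequencing was done on 10 libraries of HCT116 cells, in 4 groups taken from the sample labels: shControl (n = 2), shSMC4 (n = 2), Control (n = 3) and Starvation (n = 3). Total RNA was extracted with phenol and chloroform and sequenced on BGISEQ and Illumina HiSeq instruments, per the labels' protocols, which do not say which library went on which. Per the submitters' processing notes, HISAT2, HTSeq and DESeq2 were used with the build hg38. Their versions, roles, annotation and filters are not given in the sources used here, nor is the strand setting. Reads of a gene and its antisense partner therefore cannot be told apart, and genes with near-identical copies (IFITM, HLA, histone, metallothionein and ribosomal protein genes among those named) are uncertain to the extent that the counting split their reads.

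For the knockdown, the authors deposited an estimated count per gene and library, and 14.9% of the values are not whole. The same table holds FPKM values by the authors, and the reads these imply, checked over 124 genes, come to 97.0% to 97.3% of the summed counts. For starvation, the authors deposited FPKM per library, the mean normalized signal of each group, its fold (ratio) and a p-value and q-value per gene. Per the file headers the columns of that table name a control and a case group, and the case was matched to Starvation because the table compares starvation with control and both groups have replicates 1 to 3. The headers do not name the unit FPKM, which follows from the values in both tables. In the knockdown table a control column has a letter where the others have a replicate digit, and it was taken as shControl replicate 1. Of the gene IDs, 16838 of 17078 and 19741 of 20030 matched the GRCh38 gene table, 16997 were in both tables, and 27 symbols that a spreadsheet had turned into dates were given back by ID. From the FPKM and mean signal of the starvation table whole reads were recovered, with 100% of values within 0.05 reads of a whole number in all 6 libraries. FPKM divides by the total reads of a library, so a shift of reads into a few genes lowers all others. The 10 most abundant genes took 4.34% to 4.51% of reads in Control and 6.00% to 6.25% in Starvation, against 6.01% to 6.25% over the knockdown libraries.

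For the knockdown, estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood, robust, TMM, filterByExpr). The SE given with edgeR fold changes was worked back from the fold change and its F statistic. For starvation, where counts had been planned but FPKM was given, limma 3.58.1 (trend) was applied to log2(FPKM + 1) for genes with a group mean of at least 1 FPKM. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05, and each comparison used only its own groups. In all, 38 gene lists with 1151 genes were tested with limma's camera at a preset correlation of 0.01 where at least 5 members were tested, which 32 lists reached in each comparison. Camera with an estimated correlation and fry, which asks whether genes of a list move one way and compares it with no other genes, were run beside it. With an estimated correlation, camera rests on the few libraries of a comparison, so few lists can pass after adjustment. A call lost there leaves the list undecided. The lists of mitochondrial genome transcripts and of RNA-quality transcripts had 0 members measured. Lists of markers of other cell types are given as values. The designs, the lists, the alternative settings and the rule for named genes were fixed before the data were examined.

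By that rule the text names condensin subunits, the 8 largest rises and falls among called genes whose groups do not overlap and that reach 10 CPM or 1 FPKM in a group, up to 4 members per list with the smallest p plus members that do not follow, and 5 genes per direction for both comparisons together. Some genes that the rule picks are not reported here. Pathway genes in the closing part and words of untranslated regions were chosen after the data were seen. Coordinates are on GRCh38, and transcripts and untranslated regions are from GENCODE 29. Words of 7 bases were scanned over 3' untranslated regions of at least 50 bases, with fold changes adjusted for length, GC content and level.

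Replicates of a group were compared by chi-square over genes, which gave 1.85 to 8.56 per gene and no identical pair, so each library counts once. The alternative settings were other scalings (DESeq2 size factors, library size alone), filters (none, 5 CPM), tests (DESeq2 1.42.0, limma-voom, limma on FPKM), a pseudocount of 0.1, a fold threshold, the replicate number as a block and leaving out each replicate. With 1 library left in a group, that library is taken to vary like those of the other group. Count tests on the recovered reads, FPKM rescaled by TMM factors, the interaction test, the sets without AGCATA and the condensin list without SMC4 were added after the files were seen. Plots and the word scan used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

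The tests were tried on simulated data with known changes. For the knockdown (13220 genes), edgeR found 62.0%, 80.0%, 91.8% and 100% of genes changed 1.25, 1.5, 2 and 4-fold, and 10 unchanged genes made up 5.68% of its calls. For starvation (11475 genes), limma on FPKM found 54.8%, 90.9%, 100% and 100%, with 11 unchanged genes (6.88% of calls). With the scaling offset of the real libraries added (11499 genes), it called 2895 unchanged genes, 94.6% of its calls. These shares depend on the few genes changed in the simulations, 42 to 50 per fold, and are not error rates of the real calls. On simulated reads (13100 genes) edgeR found 56.0%, 89.8%, 92.0% and 100%, with 10 unchanged genes. In camera 10 of 10 raised lists and 1 of 100 random lists were called, and a planted word ranked first in 5 of 5 draws of the word scan.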

Results

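RNA sequencing of total RNA was carried out on HCT116, an established human colorectal cancer cell line, in 4 groups. The knockdown part held shControl cells (n = 2), which carried a control short hairpin RNA, and shSMC4 cells (n = 2), which carried a hairpin against SMC4, a core ATPase subunit of both condensin complexes. The starvation part held Control cells (n = 3) and cells kept without glucose and serum, called Starvation here (n = 3). Each part had its own table, with 17078 genes for the knockdown and 20030 for starvation, and no library entered both. The shControl libraries summed to 14312361 and 14699274 estimated reads and the shSMC4 libraries to 14273812 and 14349313. The Control libraries held 17832328, 17783406 and 17051892 reads in genes and the Starvation libraries 17318017, 16419980 and 16322854. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

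SMC4 (gene ID 10051, chromosome 3, 160399650 to 160434953 on GRCh38) was measured first in every library. It stood at 264 and 268 CPM (counts scaled to library size) in the shControl libraries and at 75.8 and 71.9 CPM in the shSMC4 libraries. The means were 266 ± 3.0 CPM (SD, n = 2) and 73.9 ± 2.79 CPM (SD, n = 2), a ratio of 0.277 and a log2 fold change of -1.85 (SE 0.05, edgeR quasi-likelihood adjusted p = 2.19e-18). Without any hairpin, SMC4 also fell in starved cells, from 43.3, 39.9 and 38.6 FPKM (fragments scaled to gene length and library size) in Control to 16.5, 15.7 and 17.1 FPKM in Starvation. The means there were 40.6 ± 2.43 (SD, n = 3) and 16.5 ± 0.692 FPKM (SD, n = 3), with a log2 fold change of -1.25 (SE 0.06, limma adjusted p = 3.36e-09).

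**Figure D1:**
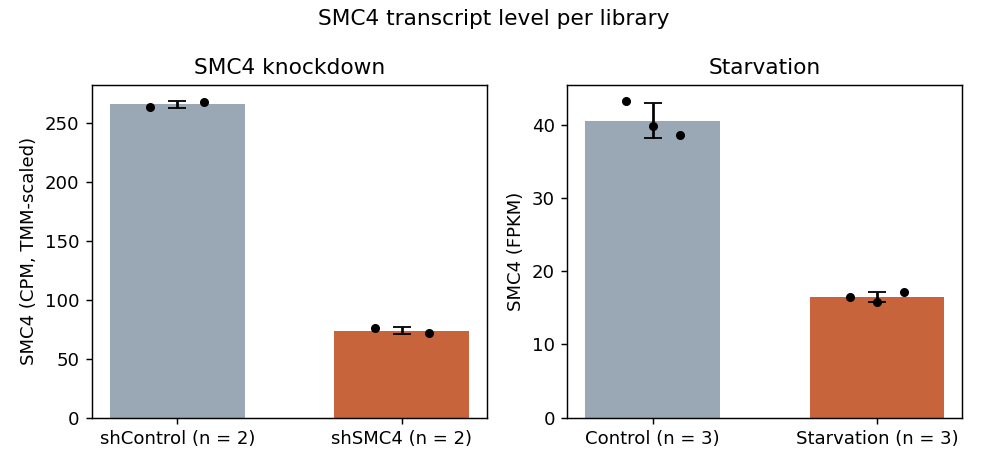
Level of SMC4 in each library, in CPM for the knockdown part (left) and in FPKM for the starvation part (right), where points are single libraries and bars are group means with SD. The shSMC4 libraries lie at 75.8 and 71.9 CPM against 264 and 268 in shControl, and the Starvation libraries lie between 15.7 and 17.1 FPKM against 38.6 to 43.3 in Control.

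The knockdown comparison asked how expression differs between SMC4-depleted and control HCT116 cells. Interferon-stimulated genes, which are switched on by antiviral signalling, rose most in shSMC4 cells (n = 2 against 2). IFI27 (gene ID 3429, chromosome 14, 94105894 to 94116690 on GRCh38), a small membrane protein induced by interferon, rose 14.2-fold, from 4.09 ± 0.528 to 58.3 ± 3.19 CPM (SD, log2 3.83, SE 0.11, adjusted p = 3e-18). DNA replication genes fell together by a smaller amount, with a median log2 change of -0.46, and so did 5 of the 7 measured condensin subunits other than SMC4. Genes of ribosome production, amino acid supply, heat shock and DNA repair also fell, while hypoxia-inducible genes, p53 targets and immediate early genes rose. Each of these list calls was lost in camera with an estimated correlation (adjusted p = 0.146 to adjusted p = 0.327 with an estimated correlation). With so few libraries per group few lists can pass that test, so the loss leaves these calls undecided.

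The 8 largest rises after IFI27 continued with IFITM1 (log2 3.53, SE 0.14), an antiviral membrane protein, OAS1 (3.47, SE 0.12), a sensor of double-stranded RNA, IFI6 (3.43, SE 0.07), IFIT1 (3.38, SE 0.07), an RNA-binding antiviral protein, and IFI44 (2.98, SE 0.17). GAL3ST1, a sulfotransferase of glycolipids, rose by 2.97 (SE 0.21) and BATF2, a leucine zipper transcription factor, by 2.65 (SE 0.16). IFI6 went from 18.9 ± 0.0790 to 203 ± 9.83 CPM and IFIT1 from 17.0 ± 0.852 to 177 ± 0.291 CPM (SD, n = 2 each). After SMC4, the largest fall was that of CBFB (gene ID 865, chromosome 16, 67029149 to 67101058), the partner subunit of RUNX transcription factors, from 102 ± 1.07 to 30.9 ± 1.43 CPM (log2 -1.72, SE 0.07). The others were SLC7A11 (-1.51, SE 0.09), the cystine and glutamate exchanger, DDAH1 (-1.38, SE 0.10), EIF5A2 (-1.35, SE 0.11), CBX1 (-1.33, SE 0.05), a heterochromatin protein, CDKN3 (-1.27, SE 0.08) and ABT1 (-1.27, SE 0.08). The 6-base word AGCATA stood in the 3' untranslated region of 6 of these 8 falling genes, all but CBX1 and CDKN3, and in 0 of the 8 rising genes. It stood in 3310 of 12850 genes with an annotated region, and it was itself found by a search for words tied to falling genes.

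Condensin, the ring complex that compacts mitotic chromosomes, had 6 of 8 measured subunits that fell, over all genes and adjusted over the list alone. Besides SMC4 these were SMC2 (log2 -0.52, SE 0.08), NCAPD3 (-0.51, SE 0.06), NCAPH (-0.37, SE 0.06), NCAPG2 (-0.27, SE 0.05) and NCAPD2 (-0.20, SE 0.05), and the word AGCATA was present in the 3' untranslated regions of SMC4, SMC2, NCAPD3 and NCAPG2. The 4 subunits without the word had a median of -0.16 and 2 of them fell, and the 4 with it had a median of -0.52. NCAPH2 (-0.12, adjusted p = 0.128) and NCAPG (-0.10, adjusted p = 0.105) did not pass. NCAPD2 missed the threshold when shControl replicate 2 was left out (adjusted p = 0.0550) and by limma on log2(FPKM + 1) (adjusted p = 0.0579), whereas NCAPH2 passed without shSMC4 replicate 2 (adjusted p = 0.0461) and NCAPG without shSMC4 replicate 1 (adjusted p = 0.00661). Set against all other genes by camera, the list with SMC4, the target of the hairpin, had an adjusted p = 4.58e-05 (adjusted p = 0.327 with an estimated correlation). Without SMC4, a test added after the result was seen, 5 of 7 subunits fell, with a median of -0.27 (camera adjusted p = 0.00122, and adjusted p = 0.327 with an estimated correlation).

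Of 43 measured interferon-stimulated genes, 39 rose and 2 fell, over all genes and adjusted over the list alone, with a median log2 change of 1.74 (camera adjusted p = 5.2e-31, and adjusted p = 0.146 with an estimated correlation). HLA-B (-0.70) and HLA-C (-0.70), which present peptides to T cells, fell. Both carried AGCATA in the 3' untranslated region, as did IRF1 (0.14), an interferon regulatory factor, which did not pass. Over the 32 members without the word 31 rose and 0 fell, with a median of 1.75. Leukocyte markers moved with this group in part, since CD68 went from 29 to 52.3 CPM (log2 0.85) and CORO1A rose by 0.54, while CD8A (0.16, adjusted p = 0.716) and LYZ (0.22, adjusted p = 0.733) did not pass. TUBB3, a neuronal tubulin that carcinoma lines also express, rose by 0.34, whereas GATA3 (0.43, adjusted p = 0.0695), PAX2 (0.15), the fibroblast markers COL1A1 (0.17, adjusted p = 0.0503) and PDGFRB (0.78, adjusted p = 0.142) and the endothelial markers VWF (0.08) and PECAM1 (0.08) did not pass. COL1A1 passed with DESeq2 size factors (edgeR adjusted p = 0.0470), library size alone (0.00741), the 5 CPM filter (0.0292) and limma on FPKM (0.0433). GATA3 passed with library size alone (edgeR adjusted p = 0.0355), the 5 CPM filter (0.0473) and without shControl replicate 1 (0.0485).

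Among 50 DNA replication genes, 49 fell over all genes and 50 adjusted over the list alone (camera adjusted p = 8.61e-23, and adjusted p = 0.146 with an estimated correlation). The replicative helicase subunits MCM4 (-0.72, SE 0.05) and MCM6 (-0.71, SE 0.05), the clamp PCNA (-0.68, SE 0.05) and the S-phase transcription factor E2F1 (-1.16, SE 0.08) were among them. POLD2 (-0.12) was the gene that passed only adjusted over the list alone, or over all genes without shSMC4 replicate 2 (adjusted p = 0.0155). In DNA repair, 24 of 36 genes fell and 0 rose, or 25 adjusted over the list alone, with a median of -0.31 (camera adjusted p = 3.22e-07, and adjusted p = 0.327 with an estimated correlation), among them MSH6 (-0.64) and FANCD2 (-0.52). Mitotic genes moved less, as 22 of 45 fell and 3 rose by either count, with a median of -0.12 (camera adjusted p = 0.00122, and adjusted p = 0.327 with an estimated correlation). Over the 33 members without AGCATA 11 fell and 3 rose, with a median of -0.07 (camera adjusted p = 0.0116). FOXM1 (-0.41, SE 0.05), a driver of mitotic transcription, fell, and CENPA (0.27), ASPM (0.23) and KIF20A (0.21) rose. Without shControl replicate 1 these 3 rises did not pass (edgeR adjusted p = 0.262, 0.0935 and 0.130), nor did CENPA without shSMC4 replicate 2 (adjusted p = 0.0980) or by DESeq2 (adjusted p = 0.176). In the cohesin and SMC5/6 list 15 of 19 genes fell and 1 rose by either count, with a median of -0.26 (camera adjusted p = 1.56e-05, and adjusted p = 0.362 with an estimated correlation). PDS5A (-0.71) and SMC3 (-0.51) were among the falls. Repressors of chromatin had 20 of 42 genes that fell and 8 that rose by either count, with a median of -0.17 (camera adjusted p = 0.00716, and adjusted p = 0.256 with an estimated correlation). HMGB1 (-0.58) and HMGA2 (-0.61) were among those that fell, and the median of the 35 members without AGCATA was -0.10.

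The ribosome biogenesis and MYC list had 36 of 45 genes that fell and 1 that rose, or 38 and 1 adjusted over the list alone, with a median of -0.28 (camera adjusted p = 1.49e-11, and adjusted p = 0.146 with an estimated correlation). ODC1 (-0.64) is the first enzyme of polyamine synthesis and CAD (-0.59) starts pyrimidine synthesis. For ATF4 targets, the genes of the amino acid response, 25 of 36 fell and 3 rose, or 25 and 4 adjusted over the list alone, with a median of -0.37 (camera adjusted p = 2.11e-07, and adjusted p = 0.150 with an estimated correlation). ASNS (-1.02, SE 0.06) makes asparagine and PSAT1 (-0.65, SE 0.05) serves serine synthesis, whereas CEBPB (0.61) and ATF3 (0.49) rose. Heat shock genes fell in 14 of 19 cases and rose in 2 by either count, with a median of -0.32 (camera adjusted p = 6.59e-06, and adjusted p = 0.161 with an estimated correlation). HSP90AA1, a chaperone, fell by 0.52. Nuclear-encoded respiratory chain genes fell in 26 of 49 cases, or 27 adjusted over the list alone, with a median of -0.15 (camera adjusted p = 1.24e-05, and adjusted p = 0.456 with an estimated correlation). That list was not called by fry (adjusted p = 0.111). The TCA cycle list had 14 of 28 genes that fell and 2 that rose, or 16 and 2 adjusted over the list alone, with a median of -0.15 (camera adjusted p = 0.000728, and adjusted p = 0.327 with an estimated correlation). IDH1 (-1.11, SE 0.06), the cytosolic isocitrate dehydrogenase, carried AGCATA and PC (0.73), pyruvate carboxylase, rose.

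Lipid synthesis genes were called with less margin. In the cholesterol synthesis list 10 of 25 genes fell and 4 rose, or 13 and 4 adjusted over the list alone, with a median of -0.15 (camera adjusted p = 0.0303, and adjusted p = 0.327 with an estimated correlation). SQLE, squalene epoxidase, fell by 0.66. The list call was lost without shSMC4 replicate 1 (adjusted p = 0.0917) and over the 21 members without AGCATA (adjusted p = 0.0509), whose median was also -0.15 (quartiles -0.30 and 0.07, against -0.34 and -0.02 for all 25). Fatty acid synthesis genes fell in 8 of 12 cases and rose in 2 by either count, with a median of -0.20 (camera adjusted p = 0.0216, and adjusted p = 0.386 with an estimated correlation). FASN, fatty acid synthase, fell by 0.43. The list call was lost without shControl replicate 2 (adjusted p = 0.0504) and over the 8 members without AGCATA (adjusted p = 0.0816), whose median was also -0.20 (quartiles -0.32 and 0.01, against -0.35 and -0.04 for all 12). In both lists the call ended with fewer members at the same median.

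Several groups rose in shSMC4 cells besides the interferon genes. Hypoxia-inducible genes rose in 19 of 25 cases and fell in 2 by either count, with a median of 0.43 (camera adjusted p = 4.41e-10, and adjusted p = 0.146 with an estimated correlation). Over the 18 members without AGCATA the median was 0.67. ADM (0.98, SE 0.06), a vasodilating peptide, NDRG1 (0.76, SE 0.05) and SLC2A1 (0.73, SE 0.05), the main glucose transporter, rose, while HIF1A (-0.71), the oxygen-regulated transcription factor itself, fell. The glycolysis list had 18 of 30 genes that rose and 4 that fell by either count, with a median of 0.18 (camera adjusted p = 0.000764, and adjusted p = 0.401 with an estimated correlation). PGAM1 (-0.72, SE 0.05) was the largest of the falls. Among p53 targets, 19 of 29 rose and 1 fell by either count, with a median of 0.28 (camera adjusted p = 3.17e-07, and adjusted p = 0.173 with an estimated correlation). GDF15 (1.30, SE 0.06), a secreted stress factor, BTG2 (1.18, SE 0.06), an antiproliferative protein, and CDKN1A (0.82, SE 0.05), the CDK inhibitor p21, rose. Immediate early genes rose in 18 of 32 cases and fell in 1 by either count, with a median of 0.39 (camera adjusted p = 3.72e-07, and adjusted p = 0.161 with an estimated correlation). FOSB (0.82) and JUN (0.73) were among the rises. Of 28 epithelial-mesenchymal and matrix genes, 13 rose and 5 fell, or 14 and 5 adjusted over the list alone, with a median of 0.24 (camera adjusted p = 0.00641, and adjusted p = 0.256 with an estimated correlation). ITGA2 (1.04, SE 0.05), a collagen receptor subunit, and CLDN4 (0.57), an epithelial tight junction protein, both rose. Intestinal differentiation genes rose in 5 of 9 cases and fell in 1 by either count, with a median of 0.44 (camera adjusted p = 0.0216, and adjusted p = 0.327 with an estimated correlation). CEACAM1 rose by 1.14. This call was lost without shSMC4 replicate 1 (adjusted p = 0.0959) and without shSMC4 replicate 2 (adjusted p = 0.0532).

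For the other lists camera gave no call. Genes of CDK inhibition and quiescence rose in 8 of 31 cases and fell in 9, with CCND1 (-0.67), cyclin D1, and FOXO3 (-0.76) among the falls. Unfolded protein response genes rose in 4 of 24 cases and fell in 9, autophagy and lysosome genes in 9 and 5 of 49, insulin and mTOR pathway genes in 7 and 8 of 30, apoptosis genes in 8 and 5 of 30, Wnt and stem cell genes in 10 and 5 of 25 and NF-kB targets in 5 and 2 of 18, each the same adjusted over the list alone. ABC transporters rose in 13 of 30 cases and fell in 7, or 14 and 7 adjusted over the list alone. Fatty acid oxidation genes rose in 8 of 19 cases and fell in 2, or 9 and 2 adjusted over the list alone, and NRF2 targets rose in 10 of 25 and fell in 7, or 10 and 11 adjusted over the list alone. Ribosomal protein genes fell in 15 of 66 cases and rose in 1, or 13 and 1 adjusted over the list alone, with a median of -0.04 (camera adjusted p = 0.162). They passed without shControl replicate 2 (adjusted p = 0.0119) and without shSMC4 replicate 2 (adjusted p = 0.000484). Replication-dependent histone genes rose in 4 of 6 cases and fell in 1 by either count (camera adjusted p = 0.0750), and passed without shControl replicate 1 (adjusted p = 0.0263). The median and the mean had opposite signs in the quiescence, mTOR pathway and NRF2 lists.

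In all, edgeR's quasi-likelihood test called 5692 of 13327 genes at a Benjamini-Hochberg adjusted p under 0.05, of which 2712 rose (47.6%) and 2980 fell. At least 2-fold changes were called for 360 genes, 311 up and 49 down, against 157 with the 5 CPM filter, 201 with DESeq2 and 106 with limma on FPKM. The split depended on the scaling, since library size alone gave 3588 rises and 2178 falls (62.2% up) and limma on log2(FPKM + 1) gave 3139 and 2027 (60.8% up). DESeq2 called 3242 genes, and 0 of the 20 list calls held with an estimated correlation in camera, where 8 of 32 lists had an unadjusted p under 0.05. Few lists can pass that form of camera with so few libraries.

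The starvation comparison asked how the same line responds to the loss of glucose and serum. Mitotic genes fell most in starved cells (n = 3 against 3): all 45 measured members fell, with a median log2 change of -2.10. KIF20A (gene ID 10112, chromosome 5, 138179112 to 138187723), a kinesin of cytokinesis, went from 55.1 ± 0.676 to 4.04 ± 0.584 FPKM (SD, log2 of FPKM + 1 -3.48, SE 0.08, limma adjusted p = 2.76e-11). The largest rise was that of DDIT3 (gene ID 1649, chromosome 12, 57516588 to 57520517), a transcription factor of endoplasmic reticulum stress. DDIT3 rose from 9.96 ± 0.827 to 182 ± 22.7 FPKM (log2 4.06, SE 0.08, adjusted p = 2.08e-11). The unfolded protein response, amino acid response, immediate early, interferon and cholesterol synthesis genes rose with it, and DNA replication, glycolysis and respiratory chain genes fell. Each of these list calls was lost in camera with an estimated correlation (adjusted p = 0.104 to adjusted p = 0.330 with an estimated correlation). Here too the few libraries per group let few lists pass that test, so the loss leaves these calls undecided.

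Starvation fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The median over all tested genes was -0.13 on that scale and -0.0005 on whole reads recovered from the table and scaled by TMM, so values from the reads are set beside it, as changes relative to that shift. The 8 largest rises were DDIT3 (4.06, reads 4.35), ATF3 (3.65, reads 4.05), NUPR1 (3.57, reads 5.24), DNAJB9 (3.53, reads 4.04), an endoplasmic reticulum co-chaperone, EGR2 (3.52, reads 4.87), EGR1 (3.5, reads 3.79), CYR61 (3.48, reads 3.91) and JUN (3.41, reads 3.83). The 8 largest falls were KIF20A (-3.48, reads -3.61), CCNB1 (-3.09, reads -3.02), cyclin B1, CDC20 (-2.98, reads -2.86), MAT2A (-2.97, reads -2.84), which makes S-adenosylmethionine, CA9 (-2.96, reads -5.40), a carbonic anhydrase, ARRDC4 (-2.90, reads -3.65), PLK1 (-2.82, reads -2.77) and TMSB15A (-2.73, reads -3.09). Their standard errors lay between 0.04 for PLK1 and 0.19 for EGR1.

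The 8 measured condensin subunits all fell, over all genes and adjusted over the list alone, with a median of -1.43 (reads -1.34, camera adjusted p = 0.000449, and adjusted p = 0.214 with an estimated correlation). NCAPD2 (-1.70, SE 0.04), NCAPG2 (-1.59), NCAPH (-1.58), NCAPG (-1.52), NCAPD3 (-1.33) and SMC4 (-1.25) fell more than SMC2 (-0.93) and NCAPH2 (-0.73) in these estimates. The mitotic list gave a camera adjusted p = 4.03e-16 (adjusted p = 0.159 with an estimated correlation), and its 45 of 45 falls were the same adjusted over the list alone, BUB1 (-2.71, SE 0.05), a spindle checkpoint kinase, among them. Of 50 DNA replication genes 49 fell by either count, with a median of -1.32 (reads -1.29, camera adjusted p = 7.79e-13, and adjusted p = 0.191 with an estimated correlation), including MCM6 (-1.91) and PCNA (-1.60), while CDT1, which licenses origins, stood at -0.02 (reads 0.14, edgeR adjusted p = 0.0461). In DNA repair 32 of 36 genes fell and 2 rose by either count, with a median of -0.81 (reads -0.90, camera adjusted p = 2.75e-05, and adjusted p = 0.307 with an estimated correlation). RAD54L, a recombination helicase, fell by 1.84, and ATM (1.02), a kinase of the DNA damage response, rose. Wnt and stem cell genes fell in 19 of 23 cases and rose in 4 by either count, with a median of -0.86 (reads -0.91, camera adjusted p = 0.00767, and adjusted p = 0.159 with an estimated correlation). AXIN2 (-1.90), a direct Wnt target, NOTUM (-1.79) and SOX4 (-1.77) fell and KLF4 (1.65) rose. The leukocyte marker CORO1A (-2.00) fell alongside these groups, as did TUBB3 (-0.77), GATA3 (-0.68) and PAX2 (-0.50), from the list of genes of embryonic kidney and neural lines.

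In glycolysis 23 of 30 genes fell and 2 rose by either count, with a median of -1.06 (reads -0.92, camera adjusted p = 2.75e-05, and adjusted p = 0.182 with an estimated correlation). LDHA, which makes lactate, went from 737 ± 14.6 to 156 ± 4.68 FPKM (-2.23, SE 0.04), and ENO2 (-2.34) and GPI (-2.04) fell too. Nuclear-encoded respiratory chain genes fell in 47 of 49 cases by either count, with a median of -0.69 (reads -0.56, camera adjusted p = 1.55e-08, and adjusted p = 0.330 with an estimated correlation), including NDUFS5 (-1.14). The TCA cycle list had 24 of 28 genes that fell and 3 that rose by either count, with a median of -0.62 (reads -0.47, camera adjusted p = 0.000383, and adjusted p = 0.161 with an estimated correlation). IDH2 (-1.93) fell and PC (0.71) rose. Fatty acid oxidation genes fell in 14 of 18 cases and rose in 2, or 14 and 3 adjusted over the list alone, with a median of -0.52 (reads -0.49, camera adjusted p = 0.0423, and adjusted p = 0.307 with an estimated correlation). CPT2 (-1.50) and CPT1A (-1.14), which carry fatty acids into mitochondria, fell, while PPARA (1.05) rose. Cholesterol synthesis genes rose in 16 of 25 cases and fell in 2 by either count, with a median of 0.86 (reads 1.04, camera adjusted p = 5.34e-07, and adjusted p = 0.141 with an estimated correlation), MSMO1 (1.93), a sterol oxidase, and INSIG1 (1.78), which holds back sterol synthesis, among them. Of 12 fatty acid synthesis genes 9 rose and 3 fell by either count, with a median of 0.38 (reads 0.59, camera adjusted p = 0.0118, and adjusted p = 0.161 with an estimated correlation). SCD, the stearoyl-CoA desaturase, rose by 1.39.

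All 24 unfolded protein response genes rose by either count, with a median of 1.26 (reads 1.5, camera adjusted p = 3.97e-14, and adjusted p = 0.104 with an estimated correlation). HSPA5, the main endoplasmic reticulum chaperone, rose from 227 ± 1.47 to 1390 ± 69.3 FPKM (2.60, SE 0.05), with HERPUD1 at 2.45 and XBP1 at 2.36. Among ATF4 targets 32 of 37 rose and 3 fell by either count, with a median of 0.73 (reads 0.91, camera adjusted p = 6.77e-12, and adjusted p = 0.159 with an estimated correlation). TRIB3 (2.94) and PPP1R15A (2.79) were among the rises. For p53 targets 22 of 29 rose and 3 fell, or 23 and 3 adjusted over the list alone, with a median of 0.47 (reads 0.64, camera adjusted p = 2.01e-07, and adjusted p = 0.159 with an estimated correlation). GDF15 (3.0) and CDKN1A (1.61) rose. Immediate early genes, many of which serum itself induces, rose in 30 of 32 cases and fell in 2 by either count, with a median of 1.23 (reads 1.44, camera adjusted p = 2.16e-12, and adjusted p = 0.141 with an estimated correlation). FOSB (3.32), DUSP5 (3.15) and MAFF (2.63) rose, and ETV4 (-0.76, reads -0.64) fell, while MYC (-0.28) passed on FPKM and not on the reads (-0.10, edgeR adjusted p = 0.550). MYC did not pass on FPKM without Control replicate 1 (limma adjusted p = 0.0814), Starvation replicate 1 (0.0841) or Starvation replicate 3 (0.135). Starvation replicate 2 stood lower than the others for several of these genes, with EGR1 at 291, 144 and 257 FPKM and EGR2 at 24.7, 12.8 and 21.5 FPKM in the 3 Starvation libraries. Interferon-stimulated genes rose in 35 of 41 cases and fell in 2 by either count, with a median of 0.85 (camera adjusted p = 1.35e-10, and adjusted p = 0.191 with an estimated correlation). On the reads 41 of 45 rose and 0 fell, with a median of 1.23, and IFITM1 (2.12), BST2 (1.98) and PARP14 (1.69) were among the rises. CD68, a macrophage marker, stood at 24.5 FPKM in Control and 25.5 in Starvation (0.05, reads 0.22, edgeR adjusted p on reads = 0.00590), and COL1A1, a fibroblast collagen, at -0.10 (adjusted p = 0.210, and 0.0283 without Starvation replicate 2). NF-kB targets rose in 10 of 15 cases and fell in 2 by either count, with a median of 0.59 (reads 0.79, camera adjusted p = 0.00244, and adjusted p = 0.203 with an estimated correlation). TNFAIP2 (1.31) and LIF (0.88) rose. Ribosomal protein genes rose in 62 of 66 cases, or 63 adjusted over the list alone, with a median of 0.36 (reads 0.52, camera adjusted p = 9.4e-13, and adjusted p = 0.345 with an estimated correlation), and RPS27 (0.65) and RPL34 (0.59) were among them.

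For the rest camera gave no call, and the counts are the same adjusted over the list alone unless given. Hypoxia-inducible genes fell in 17 of 24 cases and rose in 5 (camera adjusted p = 0.0654, and 0.0461 on the reads), with CA9 and BNIP3 (-1.81) falling and VEGFA (1.4) and BHLHE40 (1.63) rising. Epithelial-mesenchymal and matrix genes rose in 12 of 26 cases and fell in 8 (camera adjusted p = 0.0548), and on the reads in 16 and 5 of 31 (adjusted p = 0.0519). On FPKM they passed without Control replicate 3 (0.0495), Starvation replicate 1 (0.0480) or Starvation replicate 3 (0.0422). Ribosome biogenesis and MYC genes fell in 29 of 45 cases and rose in 10 (on the reads 20 and 13), and chromatin repressors fell in 24 of 39 and rose in 8 (on the reads 23 and 13 of 42). Genes of quiescence rose in 12 of 30 cases and fell in 12 (on the reads 17 and 9 of 31), and heat shock genes rose in 10 of 19 and fell in 7 (10 and 8 adjusted over the list alone, and 10 and 7 on the reads). NRF2 targets rose in 10 of 23 cases and fell in 7 (15 and 6 of 26 on the reads), apoptosis genes in 13 and 10 of 29 (14 and 9 of 30), histones in 3 and 1 of 6 (5 and 0 of 5) and intestinal differentiation genes in 3 and 2 of 6 (6 and 2 of 10). ABC transporters rose in 6 of 26 cases and fell in 20 (6 and 18 of 30 on the reads). Autophagy and lysosome genes rose in 17 of 49 cases and fell in 22 (27 and 14 on the reads), mTOR pathway genes in 11 and 13 of 30 (13 and 10) and the cohesin list in 7 and 9 of 19 (10 and 7). For these 3 lists the direction of the majority differed between FPKM and the reads, and in them and the apoptosis list the median and the mean had opposite signs.

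**Figure D2:**
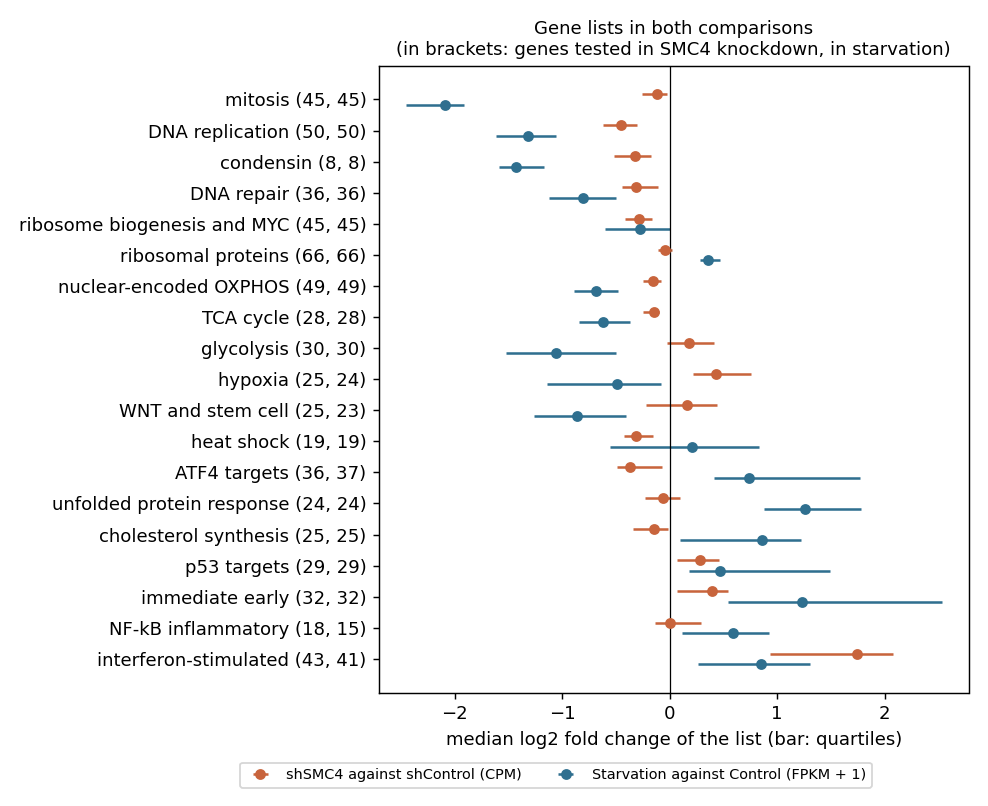
Median log2 fold change of 19 gene lists (points) with quartiles (bars) in shSMC4 against shControl (CPM, n = 2 each) and in Starvation against Control (log2 of FPKM + 1, n = 3 each), where brackets give the genes tested in each. Mitotic genes lie at -0.12 and -2.10, unfolded protein response genes at -0.06 and 1.26, and interferon-stimulated genes at 1.74 and 0.85.

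In all, limma on log2(FPKM + 1) called 9375 of 11723 genes, of which 3717 rose (39.6%) and 5658 fell, and 1580 changed at least 2-fold (507 up, 1073 down, against 706 and 767 on FPKM rescaled by TMM factors). On the recovered reads edgeR with TMM called 10235 of 13203 genes, 5123 up (50.1%) and 5112 down, with 2925 at least 2-fold (1318 up, 1607 down), and 8346 genes were called in both with the same direction and 0 with opposite directions. The authors' deposited table called 9764 of 16958 genes, 4878 up and 4886 down, of which 8078 were called here with the same direction. In simulated libraries with the scaling offset of the real ones, limma on FPKM called 2895 unchanged genes, so small FPKM falls can be that offset, and small rises can be missed. None of the 18 list calls held with an estimated correlation in camera (0 of 32 lists, with 9 at an unadjusted p under 0.05). Few lists can pass that form of camera with so few libraries.

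Set side by side, the comparisons shared directions more often than independent lists would. Of 11618 genes tested in both, 902 rose in both (750 by chance, odds ratio 1.43, Fisher's exact p = 1.07e-13) and 1682 fell in both (1408 by chance, odds ratio 1.66, Fisher's exact p = 8.56e-32). Opposite calls were fewer than chance, with 1019 genes up in shSMC4 and down in starvation (1156 by chance, odds ratio 0.747) and 742 the other way (914 by chance, odds ratio 0.683). Genes are not independent, and the comparisons share no libraries. At least 2-fold in each, 38 genes rose in both (5.99 by chance) and 4 fell (2.95 by chance), and with starvation calls from the reads 92 rose (24.2 by chance) and 5 fell (4.77 by chance). Opposite calls at that threshold on the reads were near chance, with 31 genes up in shSMC4 and down in starvation (33.2 by chance, odds ratio 0.922) and 5 the other way (3.47 by chance). On FPKM 4 genes were up in shSMC4 and down in starvation (13.2 by chance, odds ratio 0.281) and 2 went the other way (1.34 by chance). Across genes the fold changes correlated weakly, with Pearson's r 0.161 and Spearman's rho 0.127, and r was 0.141 without the interferon list. With starvation fold changes from the reads r was 0.104 and rho 0.0904.

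The largest joint rises were interferon-stimulated or lectin genes: IFITM1 (3.53 in shSMC4 and 2.12 in starvation), BST2 (2.64 and 1.98), LGALS9 (2.44 and 1.75), OAS1 (3.47 and 1.68) and DTX3L (1.74 and 1.56). The starvation value of each pair is on the log2(FPKM + 1) scale, so the sizes do not compare directly. On the reads these rises in starvation were 2.33, 2.20, 2.32, 2.05 and 1.83, in that order. The largest joint falls were EIF5A2 (-1.35 and -1.47), CDKN3 (-1.27 and -2.63), SMC4 (-1.85 and -1.25), ARL6IP1 (-1.02 and -1.52) and E2F2 (-0.99 and -1.32). EIF5A2, SMC4 and ARL6IP1 carried AGCATA in the 3' untranslated region, and CDKN3 and E2F2 did not. KRT13, a keratin (1.44 and -1.26), CA9 (1.25 and -2.96), LOXL2, a lysyl oxidase (1.12 and -1.81), DPCD (0.90 and -1.21) and MT1X, a metallothionein (0.90 and -1.35), rose after knockdown and fell in starvation. SLC7A11 (-1.51 and 1.39), AXL, a receptor tyrosine kinase (-1.06 and 1.64), KMT5B (-1.0 and 0.98), CYBRD1 (-0.76 and 0.85) and ZFAND2A (-0.74 and 1.59) went the opposite way. Of these, SLC7A11, KMT5B and CYBRD1 carried AGCATA, and AXL and ZFAND2A did not.

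The difference itself was tested by an edgeR interaction over all 10 libraries, on rounded estimated counts and recovered reads, which was added after the tables were seen. Both parts share a spread per gene in this fit, although they may come from different instruments. Chi-square per gene between replicates was 1.85 to 2.99 in the knockdown part and 2.33 to 8.56 in the starvation part. The interaction called 8897 of 13923 genes, 4486 higher in the knockdown contrast and 4411 lower, and with library size alone 9108, 6075 higher and 3033 lower. Camera with an estimated correlation rests here on more libraries than in either comparison alone, so more lists can pass it. Mitotic genes differed most among the lists, with 45 of 45 less reduced after knockdown (median difference 1.96, camera adjusted p = 1.14e-26, and adjusted p = 0.0302 with an estimated correlation). Unfolded protein response genes (-1.54, adjusted p = 0.00546 with an estimated correlation), immediate early genes (-1.38, 0.0302), ATF4 targets (-1.33, 0.0302), cholesterol synthesis (-1.16, 0.0118) and fatty acid synthesis (-0.57, 0.0331) were lower in the knockdown contrast, and Wnt and stem cell genes were higher (1.10, 0.0302). Glycolysis genes were higher by 1.14 (camera adjusted p = 5.4e-10, and adjusted p = 0.0543 with an estimated correlation). For interferon-stimulated genes the median difference was 0.36 (camera adjusted p = 0.0342, and adjusted p = 0.454 with an estimated correlation). Among the jointly called genes LGALS9 (0.10, adjusted p = 0.703) and DTX3L (-0.11, adjusted p = 0.436) showed no difference that passed, whereas OAS1 (1.4, adjusted p = 5.21e-07), IFITM1 (1.18, adjusted p = 5.1e-05) and BST2 (0.43, adjusted p = 0.0416) were higher after knockdown.

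**Figure D3:**
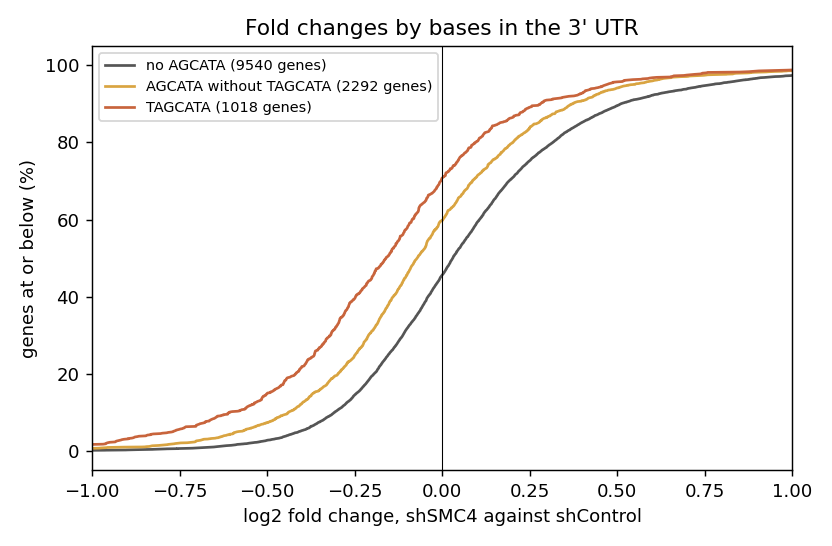
Cumulative share of genes (%, vertical) at or below each log2 fold change in shSMC4 against shControl (horizontal). Curves are drawn for genes whose 3' untranslated region held no AGCATA (n = 9540), AGCATA without TAGCATA (n = 2292) or TAGCATA (n = 1018). By edgeR's calls, which the curves do not show, 18.9% of genes with none fell, as did 54.3% of the 232 genes with the 8-base form. These 232 genes are not drawn apart from the others with TAGCATA.

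The 3' untranslated regions were searched for words shared by genes that fell in shSMC4. Of 12850 genes with an annotated region, 9540 had no AGCATA and a median log2 change of 0.03. The 232 genes with the 8-base form around it had a median of -0.28, and 54.3% of them fell against 18.9% of those with none. Genes with the word had longer regions (median 3013 against 915 bases), and in starvation, where no hairpin was used, 33.3% of genes with the 8-base form and 40.2% of those with none fell. Without the carriers edgeR's calls numbered 4000, with 2199 rises and 1801 falls. Among the falling genes named from the lists, PCNA, PDS5A, HMGA2, HSP90AA1, SQLE, PGAM1, CCND1 and FOXO3 were carriers too.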

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

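The tests on recovered reads, on genes without AGCATA and on condensin without SMC4 were chosen after the result was seen. No call turned to the opposite call, but CDT1, not called in starvation on FPKM, rose on the reads (0.143 with TMM, 0.145 with DESeq2 size factors, 0.138 unfiltered). Over the settings SMC4 lay between -1.89 and -1.75, and 165 of 181 named genes kept their call or lack of one for the knockdown and 161 of 165 for starvation. Leaving out a library gave 3878 to 5690 calls for the knockdown, 8870 to 9452 for starvation and a correlation of 0.137 to 0.178. For the knockdown DESeq2 called 3242 genes (1331 up, 1911 down), a 2-fold threshold left 360, and 2-fold calls were 157 with the 5 CPM filter, 201 with DESeq2 and 106 with limma on FPKM. Without AGCATA carriers 1801 genes fell, among fewer genes tested. For starvation a 2-fold threshold left 1580, against 2925 on the reads (TMM and also DESeq2 size factors), 3073 with library size alone, 3381 unfiltered, 3134 with DESeq2 and 2931 with limma-voom. With an estimated correlation 0 lists were called in the knockdown and 0 in starvation by camera (8 and 9 at unadjusted p under 0.05), and fry called 31 in starvation. Genes shared at 2-fold were 42, and 97 on the reads, where the correlation was 0.104. Same-numbered libraries did not deviate together (r -0.0905 for the knockdown, 0.0549, 0.0504 and 0.00165 for starvation, where Starvation 3 went best with Control 1, 0.0108). With the replicate number as a block 5150 and 9463 genes were called, and of lists fatty acid synthesis lost its call (0.0552) and the starvation matrix list gained one (0.0474). Other causes were not tested. At these depths the simulations found 62.0% and 54.8% of 1.25-fold changes.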

Other observations

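Pathways from the annotation in the starvation table, the interferon, vector and ribosomal tests below and their explanations were chosen after the result was seen. Of 307 pathways tested for the knockdown camera called 34, and of 298 for starvation 33, but 0 in either with an estimated correlation (10 and 14 at an unadjusted p under 0.05). With so few libraries few pathways can pass that form of camera. Spliceosome genes fell in 92 of 129 cases after SMC4 knockdown and rose in 0, with a median log2 change of -0.29 (camera adjusted p = 9.23e-17, and adjusted p = 0.809 with an estimated correlation). SNRNP200 (-1.05), a helicase of the spliceosome, SRSF3 (-0.88) and SRSF2 (-0.59), splicing factors, carried AGCATA, and HNRNPC (-0.52) did not. Over the 96 members without the word 63 fell, with a median of -0.25. Proteasome genes fell in 33 of 42 cases in the knockdown (median -0.33, camera adjusted p = 1.81e-09, and adjusted p = 0.809 with an estimated correlation) and in 36 of 41 in starvation (median -0.76, camera adjusted p = 1.81e-06, and adjusted p = 0.679 with an estimated correlation), PSMD2 (-0.43 and -1.53) among them. Genes of contact with the extracellular matrix rose in 24 of 53 cases after knockdown and fell in 5 (median 0.35, camera adjusted p = 1.12e-05, and adjusted p = 0.809 with an estimated correlation), including the integrins ITGA2 (1.04), ITGB4 (0.76) and ITGA3 (0.56).

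A first hypothesis is that part of the falls in shSMC4 cells comes from off-target silencing, in which the hairpin's guide acts like a microRNA through its seed. Of 15933 words of 7 bases in 3' untranslated regions, TAGCATA had the most negative shift (z -12.3 over 1018 genes, against a Bonferroni limit of -4.52 and -4.79 as the lowest of 5 permutations), while its z in starvation was 1.75. The overlapping words GTAGCAT (-11.1) and AGCATAA (-11.0) came next, and 14 words passed downward and 2 upward, against 0 and 3 in starvation (lowest z -4.35, limit -4.52). Whether the word belongs to this hairpin cannot be told apart from a microRNA with the same seed, since the guide is not given. SMC4 holds the word 1 time, at base 2631 of its longest transcript (exon 14 of 24, coding, chromosome 3, 160423585 to 160423591 on GRCh38). The base on its left there is that of GTAGCAT, and 3.44% of 1481 transcripts of like length hold the word with that base. The word alone is held by 14.8% of them. The base on its right is not that of AGCATAA but gives AGCATAT, which ranked 5 among the words (z -8.76). Such a match also occurs in other transcripts, so it does not settle the question. For DNA replication, members without AGCATA had a median of -0.45, which argues against direct silencing through this word as the whole cause there. Falls that follow from the silencing of another gene cannot be told from these values. Off-target silencing may account for part of the falls named.

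The rise of interferon-stimulated genes in shSMC4 cells could come from other cells, from the hairpin or its vector, or from the loss of SMC4. Cells of another type are left open for leukocytes. Their 8 markers had medians of 0.384 and 0.544 CPM in shControl and 0.736 and 0.732 in shSMC4, too low to decide. Marker levels here are scaled to library size alone. On that scale CD68 stood at 27.5 and 29.2 CPM in shControl and at 54.5 and 52.5 CPM in shSMC4. By edgeR's calls CD68 and CORO1A rose. Medians of 9 fibroblast markers stayed at 0.0701 CPM at most, and those of 6 endothelial markers were 0.140 and 0.418 CPM in shSMC4 against 0.349 and 0.340 in shControl. A response to the hairpin or vector of the shSMC4 cells cannot be told apart from the loss of SMC4. These cells were compared only with shControl, which carried a control hairpin. The labels do not say whether the shSMC4 libraries carried the same hairpin. The same genes had a median log2 change of 1.23 on the reads in starved cells, in which SMC4 was also lower, so these cells raise them without a hairpin.

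Ribosomal protein transcripts, which are short and abundant, rose in starvation with a median log2 change of 0.36. The highest median of 10000 lists matched on length, GC and level was 0.320. To the extent that the lists matched, which was not measured, this argues against bias in these as the whole cause. Genes of a list were drawn separately, so the lists do not carry the shared movement of ribosomal protein genes. The cause is left open. The 6 libraries of starvation allow 10 splits, which are too few for a share under 0.05: the real split gave 9375 genes and was the 1 split to reach that number, and the highest other gave 0 in limma, where 3 to 35 genes had an unadjusted p under 0.05.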
